A study of Homo sapiens with 8 samples.

How the data were processed

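Gene expression was measured on 8 Affymetrix arrays hybridised with biotin-labelled total RNA of ALL-SIL, an established T-cell acute lymphoblastic leukemia line that expresses the homeobox gene TLX1. The 8 arrays formed 4 groups of 2. Cells transduced with a T-cell receptor (TCR) and GFP vector were either grown for 48 h on OP9-DL1, a mouse stromal line that presents the Notch ligand DL1, or kept without co-culture. In the other experiment, cells received either a hairpin against TLX1 or the control hairpin vector. Groups and replicate numbers were taken from the sample titles, and the co-culture from the sample characteristics. Nothing in the labels says that the replicates came from separate cultures, so the p-values measure the spread between these arrays, which may be technical.

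The deposited table held log2 probe set values of all 8 arrays, which the authors made with RMA in the affy package of R 2.9.0, per the submitters' processing notes. The RMA background and summary settings were not given in the sources used here. Every array had the same lowest value, 2.15, and the same highest value, 14.3, and the array medians lay between 5.29 and 5.30, as quantile normalization over all arrays leaves them. For such values the number of arrays limits the precision, and an overall shift between arrays cannot be seen after this normalization. Of 54675 probe sets, 41097 were listed with 1 gene symbol, 1801 with several and 11777 with none in the platform annotation, and no gene was named from the last 2 kinds. Through the gene identifier, 41043 of the probe sets with 1 symbol matched the reference gene table and 0 symbols changed.

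From there, a probe set was kept when its value lay above the array median in at least 2 of the 8 arrays, which 30816 probe sets did. Each gene was represented by its kept probe set with the highest mean over all arrays, which gave 13102 genes. The test was limma's moderated test (limma 3.58.1 in R 4.3.3): 1 model with a mean for each of the 4 groups, lmFit and eBayes with default settings, and Benjamini-Hochberg adjustment over all genes tested, with a threshold of 0.05. The residual degrees of freedom were 4 and the prior degrees of freedom 3.62. The contrasts were TCR activation minus no activation, TLX1 hairpin minus control hairpin, and the difference of these 2 changes. The first 2 contrasts share no arrays. An adjusted p in the text is from this model unless another test is named, and a value given as mean ± SD is over the 2 arrays of a group. Intervals are 95% confidence intervals with the moderated standard error.

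Gene groups were 19 lists written before the data were examined: TCR complex and proximal signalling, TCR-induced transcripts, pro-apoptotic genes, anti-apoptotic genes, cell cycle, MYC targets and ribosome biogenesis, Notch targets, NF-kB targets, cortical thymocyte markers, post-selection T cell markers, T-cell leukemia transcription factors, interferon response, p53 targets, cholesterol synthesis, glycolysis, ER stress and amino acid response, fibroblast and stromal markers, B-cell and myeloid markers, and NK and cytotoxic markers. The lists name 429 different genes, of which 333 were tested, 54 were too dim and 42 had no probe set of their own. Some genes stand in more than 1 list. Each list was tested against the other genes with camera of limma at a preset inter-gene correlation of 0.01, adjusted over the 19 lists of a contrast. Camera with an estimated correlation and fry were the alternatives. Fry asks another question, as it tests a list against no change and not against the other genes. Another 4 lists (granulocyte granule genes, general myeloid genes, heat shock genes and hypoxia genes) were written after the data had been seen and are described without a test.

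The genes named were fixed by a rule before the data were examined: TLX1; in each contrast the 10 largest rises and 10 largest falls among genes past the threshold whose 2 arrays of one group all lay above those of the other in their values; up to 4 members of each list with the smallest p in a contrast; among genes past the threshold in both contrasts, the 5 per direction with the largest smaller change of the 2; and the 5 largest differences between the responses in each direction. Genes on chromosome Y are not named, nor are genes of probe sets that name several. A gene named outside the rule is said to have been chosen after its values were seen.

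The fits were tested on simulated values with the spread of each group as measured, and with 50 genes at a log2 change of 1 and 50 at 2 per contrast among 13102. For the TCR contrast 32 of the 50 smaller and 47 of the 50 larger changes were recovered, and 0 unchanged genes were called. For the TLX1 contrast 38 and 45 were recovered, but 56 unchanged genes were called as well. A second simulation was added after that count was seen: in 20 draws with no change at all, the TLX1 contrast called between 0 and 5 genes, with a median of 0, and the TCR contrast called 0 in every draw. A simulated shift of 0.5 in the cell cycle list was found by camera, with 0 of the other lists called. The simulated genes varied independently of each other, while the estimated inter-gene correlation in the data was as high as 0.68, for glycolysis. The shift was also larger than any median of a list called for TCR activation. This simulation therefore could not show whether correlated genes lead to false list calls.

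The alternatives, listed before the data were examined, were a fit with only the 2 groups compared, the replicate number as a block, no filter or a stricter filter on dim probe sets, the mean of a gene's probe sets, each probe set on its own, eBayes with trend or robust, array weights, repeated quantile normalization, centring on array medians, a 2-fold minimum, an adjusted p under 0.01, and leaving out each array. A group left with 1 array was assumed to vary like the other groups. A crossed replicate block, a count without chromosome Y genes and camera with an estimated correlation while each array was left out were added after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.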

Results

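The data comprised 8 expression arrays of the T-cell leukemia line ALL-SIL in 4 groups of 2: TCR-transduced cells after 48 h on OP9-DL1 stroma, TCR-transduced cells without co-culture, cells with a hairpin against TLX1, and cells with a control hairpin. Over all probe sets, arrays of the same group correlated at r = 0.997 to 0.998 in the TCR experiment and at 0.986 to 0.993 in the hairpin experiment. Arrays of different groups correlated at 0.993 to 0.995 within the TCR experiment and at 0.986 to 0.994 within the hairpin experiment. By this measure the hairpin arrays did not separate by group. Arrays of different experiments correlated at 0.942 to 0.951. The median SD over genes was 0.06 without co-culture and 0.04 after TCR activation (log2, n = 2 each), against 0.17 in the control hairpin group and 0.11 in the TLX1 hairpin group. RNA measures also separated the experiments: the 3′ minus 5′ signal of actin, which grows as RNA is degraded, was 2.50 ± 0.17 in the TCR experiment and 0.72 ± 0.12 in the hairpin experiment (log2, SD, n = 4 arrays each), and the 18S ribosomal RNA signal was 12.09 ± 0.09 against 8.65 ± 0.38. The same measure for GAPDH differed less, at 0.31 to 0.36 in the TCR arrays and -0.01 to 0.08 in the hairpin arrays. The source of these differences was not tested.

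The first comparison asked how the leukemia cells changed when the TCR-expressing cells were placed on the stroma, and it does not separate stroma, Notch ligand and TCR engagement. The 6 chromosome Y genes past the threshold fell by a median of -4.37 on the log2 scale. A difference between the cells of the 2 groups is therefore not separated either. Genes of granulocyte granules were among the largest rises. RNASE2, a ribonuclease of eosinophil granules, rose from 3.94 ± 0.10 to 8.99 ± 0.03 (log2, mean ± SD, n = 2 arrays per group; limma adjusted p = 1.29e-06). DEFA4, a neutrophil defensin, rose from 5.67 ± 0.13 to 9.02 ± 0.03 (adjusted p = 2.87e-05). PRTN3, the granule protease proteinase 3, rose by 3.33 on the log2 scale, and PRG2, the eosinophil major basic protein, by 2.83. The vesicle fusion gene VAMP8 rose by 3.56, the glutathione transferase gene MGST1 by 3.24 and BEX1 by 3.17. Rises were also seen for the neutrophil-attracting chemokine CXCL8 (2.95), the imprinted gene MEST (2.93) and the protease inhibitor CSTA (2.88). Apart from DEFA4 and PRG2, these genes read below the array median without co-culture, so the sizes of their rises are not exact.

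Among the falls outside chromosome Y, ADTRP, a regulator of tissue factor pathway inhibitor, went from 8.43 ± 0.11 to 5.87 ± 0.10 (log2 change -2.56, limma adjusted p = 0.00126). CD55, which protects cells from complement, changed by -2.13, the stress-activated kinase gene MAP3K20 by -2.08, the inducible heat shock gene HSPA6 by -2.00 and the prion protein gene PRNP by -1.78. The deubiquitinase gene YOD1 changed by -1.58, the mitophagy receptor gene BNIP3 by -1.35, the metalloprotease gene ADAMTS17 by -1.24, ECRG4 by -1.22 and the early-response nuclear receptor gene NR4A2 by -1.12. YOD1 read below the array median after co-culture, so the size of its fall is not exact.

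**Figure D1:**
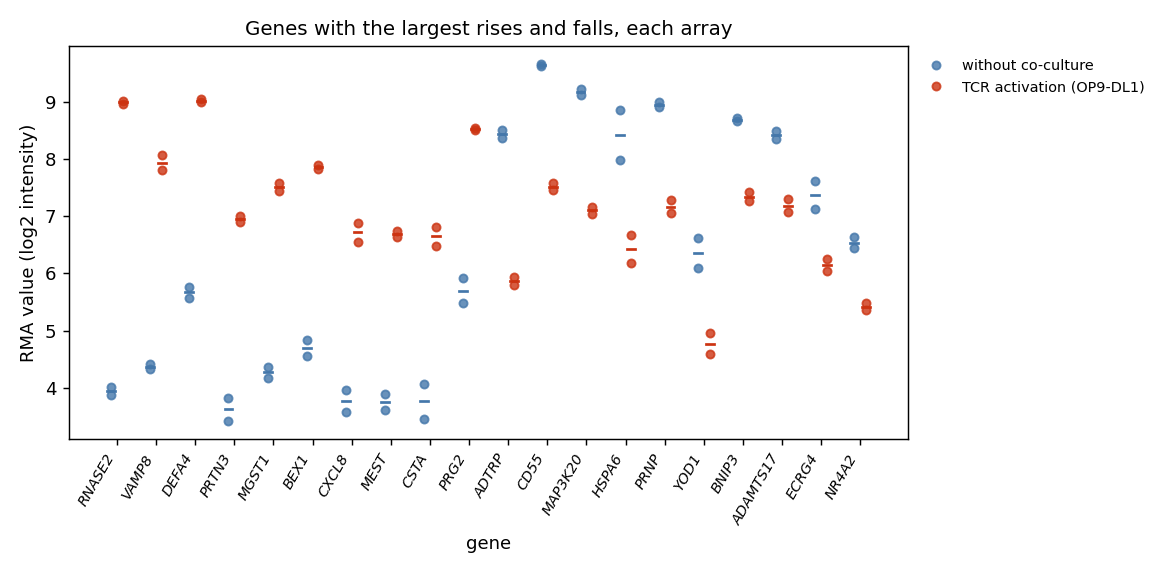
RMA values (log2 intensity, y axis) of the 10 genes with the largest rises and the 10 with the largest falls, chromosome Y genes left out (x axis), in each array without co-culture (blue) and after TCR activation (red). Points are arrays and bars are group means of 2 arrays. The 2 arrays of a group lay apart from those of the other group for every gene shown, as the rule that chose the genes requires, with RNASE2 at 3.94 and 8.99 on average.

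In all, 81 of 13102 genes passed the threshold, 48 higher and 33 lower, of which 42 and 19 changed at least 2-fold. At an unadjusted p under 0.05 there were 972, where chance gives 655. Of the 33 lower genes, 6 lie on chromosome Y, with a median change of -4.37, and 75 genes remained without them. Left-out arrays moved the count to 38 without no_TCR_activation replicate 1, 30 without its replicate 2, 29 without TCR_activation replicate 1, 32 without its replicate 2, and 217 without either shRNA_control array. The spread shared with the hairpin arrays exceeds that of the TCR arrays: 866 genes passed (466 higher, 400 lower) when only the 2 TCR groups were fitted, and 1350 (743 and 607) with array weights. Of the list members that the naming rule picks and that did not pass, 23 did in the fit of the 2 groups, among them S1PR1 (adjusted p = 0.00745), CDKN1A (0.0151) and CCNE1 (0.0184). The 10 rises passed the threshold whichever array was left out, as did ADTRP and MAP3K20. The other 8 falls each lost their call under at least 4 of the 8 left-out arrays, with an adjusted p of up to 0.109 for CD55 (without no_TCR_activation replicate 1) and 0.438 for ADAMTS17 (without TCR_activation replicate 1). With the mean of a gene's probe sets, NR4A2 (adjusted p = 0.119) and ADAMTS17 (0.0642) lost their calls, and CXCL8 lost its call without the dim filter, where another probe set represents it with a change of 0.58 (adjusted p = 0.224).

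TCR-induced transcripts, the genes that T cells switch on after receptor engagement, were lower in the co-cultured arrays as a list, with a median log2 change of -0.25 over 24 genes (camera adjusted p = 3.39e-04; adjusted p = 0.394 with an estimated correlation). Of these 24, 1 fell, 0 rose and 23 did not pass, and adjusted over the list alone again only NR4A2 fell. By sign, 20 of the 24 were lower. Without no_TCR_activation replicate 2, which stood above the other 3 arrays of the experiment (list deviations of 0.23 against -0.04, -0.14 and -0.13), the median was -0.12 (adjusted p = 0.0192; 0.636 with an estimated correlation), and with no dim filter it was -0.13 (adjusted p = 0.0411). The early-response gene FOS stood at 6.87 ± 1.40 without co-culture and 5.33 ± 0.03 after it (adjusted p = 0.525; a difference of -0.54 without no_TCR_activation replicate 2, and of -2.53 with an adjusted p of 0.00608 without its replicate 1), and CD83 at 7.60 ± 0.46 and 7.04 ± 0.04. NF-kB targets had a median change of -0.22 over 19 genes (camera adjusted p = 0.00240; adjusted p = 0.394 with an estimated correlation). By limma 0 of the 19 passed over all genes, with 2 higher and 5 lower at an unadjusted p under 0.05. Adjusted over the list alone, 4 fell and 2 rose: the subunit gene NFKB1 (-0.62), the adhesion receptor CD44 (-0.69), the inhibitor NFKBIA (-0.94) and the feedback regulator TNFAIP3 (-1.13) fell, and CCL5 (0.55) and LTA (0.57), which are named here after their values were seen, rose. Over all genes, NFKB1 (adjusted p = 0.0133), CD44 (0.00958) and TNFAIP3 (0.0152) passed in the fit of only the 2 groups, and without either shRNA_control array (0.0223, 0.0273 and 0.0291).

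Post-selection T cell markers had a median change of -0.22 over 21 genes (camera adjusted p = 0.00240; adjusted p = 0.378 with an estimated correlation). FOXO1, a transcription factor of quiescent T cells, fell by 1.10 and TXNIP, a brake on glucose uptake, rose by 1.19, while 19 did not pass. The FOXO1 call was lost without any single array of the TCR experiment or the TLX1 hairpin group, with an adjusted p of up to 0.477 without TCR_activation replicate 1. The TXNIP call was lost without no_TCR_activation replicate 2 (0.0675) and TCR_activation replicate 1 (0.0747). Adjusted over the list alone, 6 fell, among them S1PR1, the receptor for exit from the thymus (-0.73), and the cytokine receptor IL7R (-0.62), and 2 rose. Notch targets had a median of -0.10 over 17 genes (camera adjusted p = 0.0288; adjusted p = 0.394 with an estimated correlation). By limma 0 of the 17 passed over all genes, with 1 higher and 2 lower at an unadjusted p under 0.05, and adjusted over the list alone the Notch effector HES1 (-0.94) and IL7R fell and 0 rose. The Notch feedback gene NRARP stood at 6.41 and 6.66 and DTX1 at 9.56 and 9.10. Without no_TCR_activation replicate 1, the adjusted p was 0.0524 for both the post-selection list (median -0.17) and the Notch list (median -0.14). Without its replicate 2 it was 0.0751 for the Notch list (median -0.13), so the Notch median did not shrink without either array. The Notch call also ended with no dim filter (median -0.08, 0.0526) and with the mean of a gene's probe sets (median -0.10, 0.0583). Over all genes, HES1 (0.0253), IL7R (0.0158) and DTX1 (0.0235) passed in the fit of only the 2 groups, and IL7R (0.0273) without either shRNA_control array.

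Growth-related lists were higher. The cell cycle list had a median change of 0.15 over 30 genes, 26 of them higher by sign (camera adjusted p = 4.45e-04; adjusted p = 0.394 with an estimated correlation). By limma 0 of the 30 passed over all genes, with 4 higher and 0 lower at an unadjusted p under 0.05. Adjusted over the list alone, the G1/S cyclin CCNE1 rose by 0.61. The replication clamp gene PCNA stood at 12.12 and 12.41 and the mitotic kinesin gene KIF11 at 9.76 and 10.11. MYC targets and ribosome biogenesis genes had a median of 0.23 over 22 genes, 21 of them higher by sign (camera adjusted p = 0.00240; adjusted p = 0.724 with an estimated correlation). By limma 0 of the 22 passed either over all genes or adjusted over the list alone, with 4 higher and 0 lower at an unadjusted p under 0.05. RRP12 stood at 6.12 and 6.57 and the nucleolar gene FBL at 11.31 and 11.56.

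Among 18 pro-apoptotic genes, BCL2L11, which encodes the BH3-only protein BIM, fell by 0.65 (adjusted p = 0.0385) and 17 did not pass, with the same count adjusted over the list alone and 3 higher and 2 lower at an unadjusted p under 0.05. BMF stood at 7.98 and 8.44 (adjusted p = 0.340). The BCL2L11 call was lost without any single array of the TCR experiment or the TLX1 hairpin group, with an adjusted p of up to 0.488 without TCR_activation replicate 2, and also with eBayes trend (0.0544) and the stricter dim filter (0.0626). Of 12 anti-apoptotic genes, 0 passed over all genes by limma and 0 were higher and 2 lower at an unadjusted p under 0.05; TNFAIP3 fell adjusted over the list alone, and MCL1 stood at 10.83 and 10.59. The list medians were 0.00 and -0.05 (camera adjusted p = 0.656 and 0.206). Among p53 targets the median was -0.03 over 17 genes (camera adjusted p = 0.195), with 0 past the threshold over all genes by limma, 0 higher and 3 lower at an unadjusted p under 0.05, and the same 3 lower adjusted over the list alone: GADD45A (-0.73), CDKN1A (-0.84) and TP53INP1 (-0.53).

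Of the T cell identity lists, 2 besides the post-selection markers were not called by camera. TCR complex and proximal signalling genes had a median of -0.02 over 21 genes (adjusted p = 0.656) and cortical thymocyte markers of 0.00 over 17 (adjusted p = 0.919), with 0 passing by limma in either, over all genes or adjusted over the list alone; at an unadjusted p under 0.05 the first had 1 higher and 2 lower and the second 0. The phosphatase gene PTPRC stood at 8.34 and 7.73 and the TCR constant gene TRBC1 at 10.27 and 10.82. Among 15 T-cell leukemia transcription factors (median -0.03, adjusted p = 0.992), the oncogene LMO2 rose from 4.48 ± 0.30 to 5.83 ± 0.26 (adjusted p = 0.0284; up to 0.263 without TCR_activation replicate 2). LMO2 read below the array median without co-culture, so the size of its rise is not exact. TLX1 itself stood at 8.65 and 8.63. Single members also rose in 2 metabolic lists without a list shift: PFKM, the muscle-type phosphofructokinase, by 0.99 in glycolysis (median 0.05, adjusted p = 0.656), and TRIB3, a pseudokinase of the amino acid response, by 1.32 in the ER stress list (median -0.07, adjusted p = 0.966). Both calls were lost without any single array of the TCR experiment, with an adjusted p of up to 0.335 for PFKM without TCR_activation replicate 2 and 0.0993 for TRIB3 without TCR_activation replicate 1. Interferon response genes (median -0.06, adjusted p = 0.334) and cholesterol synthesis genes (median 0.05, adjusted p = 0.919) had 0 members past the threshold by limma, over all genes or adjusted over the list alone, with 1 higher and 2 lower and with 1 higher and 0 lower at an unadjusted p under 0.05.

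Lists for other cell types gave the following. Fibroblast and stromal markers, which would mark carry-over of OP9-DL1 RNA as far as human probe sets read mouse transcripts, had a median change of 0.02 over 20 genes (camera adjusted p = 0.992), and 0 passed at an adjusted or unadjusted p under 0.05 by limma. The list was 0.21 higher without TCR_activation replicate 2 (adjusted p = 0.0248) and changed by -0.10 without TCR_activation replicate 1 (adjusted p = 0.0116). With an estimated correlation the adjusted p values were 0.663 and 0.666. The list stood higher in 1 array of each group, and the collagen gene COL3A1, named after its values were seen, read 6.18 and 7.78 in the 2 arrays without co-culture, 7.54 and 6.01 in the co-cultured arrays, and 3.32 to 3.65 in the hairpin arrays. Among 9 B-cell and myeloid markers, the myeloid transcription factor CEBPA rose by 1.05 (adjusted p = 0.00510; up to 0.120 without TCR_activation replicate 1), while the granule peroxidase MPO stood at 8.69 and 7.97 and fell when adjusted over the list alone; the list median was 0.04 (camera adjusted p = 0.656). NK and cytotoxic markers had a median of -0.05 over 9 genes (adjusted p = 0.919), 0 past the threshold by limma either over all genes or adjusted over the list alone, and 1 higher at an unadjusted p under 0.05. With an estimated correlation 0 of the 19 lists were called by camera in this comparison, and 0 by the directional test of fry. In each, 2 lists had an unadjusted p under 0.05. The mixed test of fry, which counts changes in either direction, called 4 lists.

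**Figure D2:**
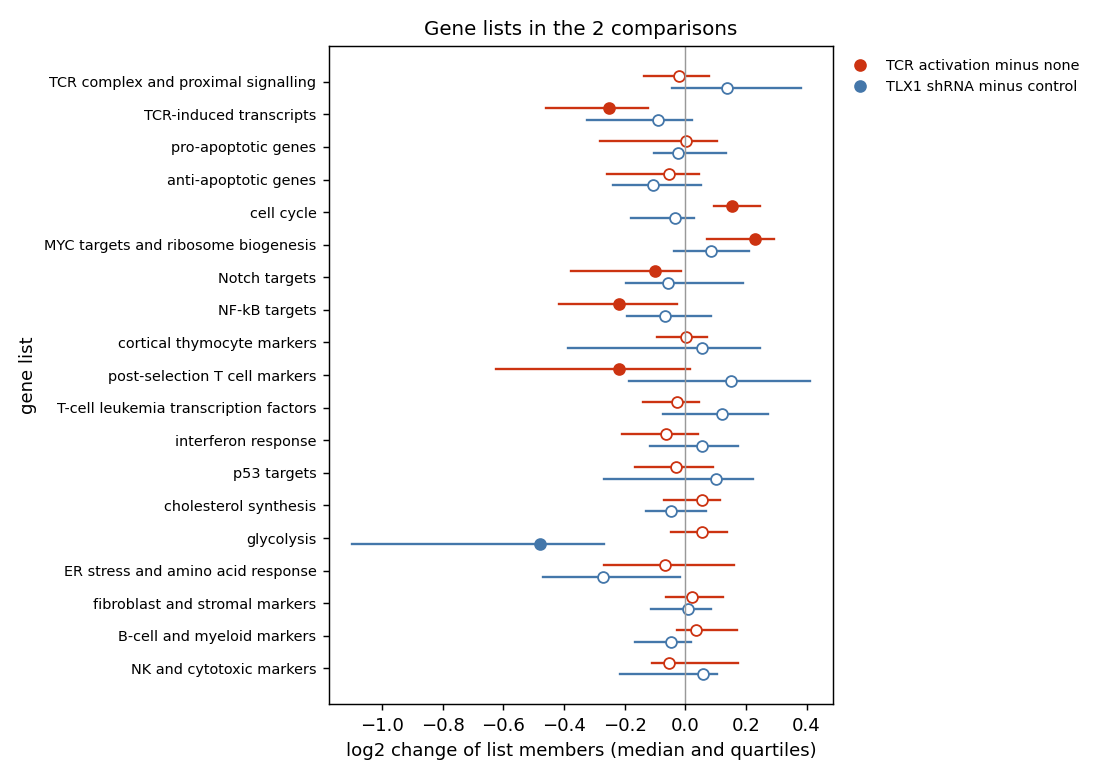
Log2 change (x axis) of the members of the 19 lists (y axis) for TCR activation minus none (red) and TLX1 shRNA minus control (blue); circles are medians, lines join the quartiles, and filled circles have a camera adjusted p under 0.05 at the preset correlation. Glycolysis had the lowest median, -0.48, in the hairpin comparison, and TCR-induced transcripts the lowest, -0.25, in the TCR comparison.

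The second comparison asked what changed when TLX1 was targeted. TLX1 (with 1 probe set) read 8.66 and 8.27 in the control hairpin arrays and 7.98 and 7.88 in the TLX1 hairpin arrays, and 8.70, 8.60, 8.69 and 8.57 in the 4 arrays of the TCR experiment. Its change was -0.53 (SE 0.15, 95% interval -0.88 to -0.19), in the direction the labels name in both arrays. That interval uses the spread shared with the TCR arrays, which understates that of the hairpin arrays, so it is probably too narrow. The limma adjusted p of TLX1 was 0.9998 when only the 2 hairpin groups were fitted and 0.9999 with array weights. In the full model TLX1 did not pass the threshold either (limma adjusted p = 0.334). Among the genes that passed, ADAMTS17 rose from 4.97 ± 0.41, below the array median, to 7.60 ± 0.02 (n = 2 arrays per group; adjusted p = 0.0142), and ID2, an inhibitor of basic helix-loop-helix factors, rose 4.75-fold from 8.23 ± 0.30 to 10.47 ± 0.28 (adjusted p = 0.0326). The thymus and gut homing receptor CCR9 went from 9.05 ± 0.04 to 7.42 ± 0.18 (log2 change -1.63, adjusted p = 0.0222).

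The other rises were the kinase gene MAP2K2 (1.25), the chromatin remodelling gene DPF3 (1.23), the Rac activator TIAM1 (1.14), RESF1 (1.07), FAM171A1 (0.87) and TSHZ3 (0.87). The other falls were SLA2, an adaptor that dampens TCR signalling (-1.40, with 0.73 for its second probe set), CIBAR1 (-1.23) and the spindle checkpoint gene MAD1L1 (-1.02). These made 12 of 13102 genes, 8 higher and 4 lower, where 1177 had an unadjusted p under 0.05 and chance gives 655. The shared spread understates that of the hairpin arrays, whose median SD was 0.17 and 0.11 against 0.06 and 0.04 in the TCR groups. When only these 2 groups were fitted with limma, 0 genes passed and 421 had an unadjusted p under 0.05. That fit also has fewer residual degrees of freedom, so the loss is not due to spread alone. In simulations of this comparison, 56 unchanged genes were called in 1 run and 0 to 5 in each of 20 draws with no change. The count was 0 without any single array of the TCR experiment or of the TLX1 hairpin group (769 to 1299 at an unadjusted p under 0.05), 1796 without shRNA_control replicate 1 and 38 without shRNA_control replicate 2. Each of the 12 genes lost its call under at least 6 of the 8 left-out arrays. With the mean of a gene's probe sets, DPF3 (adjusted p = 0.123), RESF1 (0.0729), TSHZ3 (0.0921) and SLA2 (0.570) lost theirs.

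**Figure D3:**
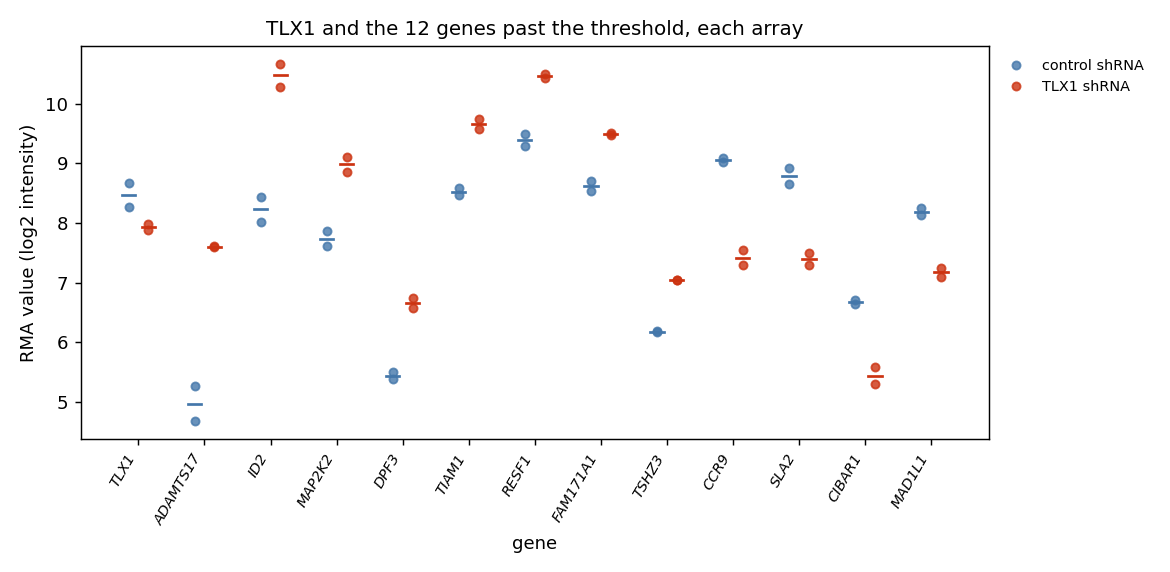
RMA values (log2 intensity, y axis) of TLX1 and the 12 genes past the threshold (x axis) in each control hairpin array (blue) and TLX1 hairpin array (red); points are arrays and bars are group means of 2 arrays. TLX1 read 8.66 and 8.27 in the control arrays and 7.98 and 7.88 in the TLX1 hairpin arrays.

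Thymocyte markers passed mostly when adjusted over the list alone, with a shared spread that understates that of the hairpin arrays. Of 17 cortical thymocyte markers, 0 passed over all genes by limma, with 3 higher and 4 lower at an unadjusted p under 0.05. Adjusted over the list alone, the lipid-presenting molecules CD1A (-0.96), CD1B (-0.93) and CD1E (-0.76) and the recombinase gene RAG1 (-0.90) fell, and CD8A (0.49) and AEBP1 (0.50) rose. Without shRNA_control replicate 1 the changes were -0.86 for CD1A, -0.83 for CD1E and -1.08 for RAG1. Without its replicate 2 the change of CD1A was -1.07. Each of these values rests on 1 control array, and the 2 control arrays differed from each other. The list median was 0.06 and its mean -0.07 (camera adjusted p = 0.642). Among 21 post-selection markers CCR9 fell over all genes and 20 did not pass, and adjusted over the list alone CCR9, CCR4 (-0.93) and CCR7 (-3.06) fell and GIMAP8 (1.26), ITGB7 (0.44) and KLF3 (0.41) rose; the last 2 are named here after their values were seen. CCR7, the lymph node homing receptor, varied widely, at 8.57 ± 0.93 in control and 5.50 ± 1.59 in TLX1 hairpin arrays. The list median was 0.15 and its mean -0.02 (camera adjusted p = 0.642).

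Glycolysis genes were lower as a list, with a median change of -0.48 over 20 genes, 19 of them lower by sign (camera adjusted p = 3.22e-07; adjusted p = 0.866 with an estimated correlation). By limma 0 of the 20 passed, over all genes or adjusted over the list alone, with 9 lower at an unadjusted p under 0.05. The enzyme gene TPI1 stood at 11.78 ± 0.72 and 10.74 ± 0.16 and the glucose transporter gene SLC2A3 at 8.47 ± 1.38 and 6.91 ± 0.00. The control arrays differed from each other, with list medians of 9.35 and 10.8 against 9.21 and 9.59 in the TLX1 hairpin arrays. Without shRNA_control replicate 2 the median change was -0.15 (adjusted p = 0.0253; 0.930 with an estimated correlation), a loss of 68.4% of its size.

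**Figure D4:**
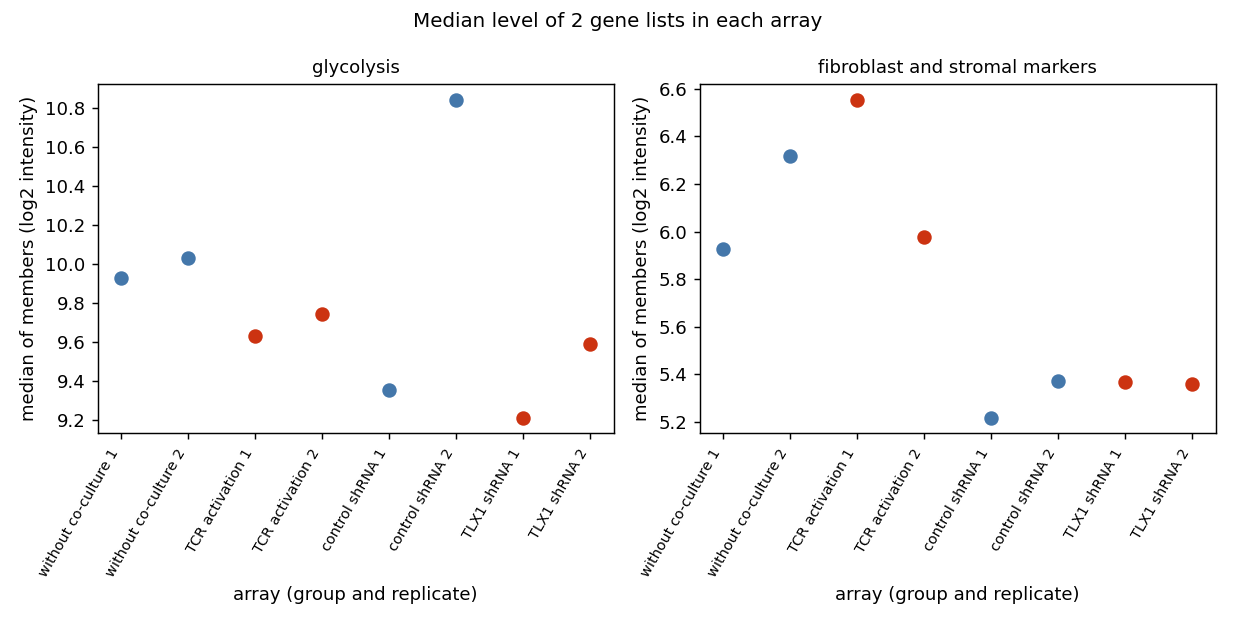
Median level (log2 intensity, y axes) of the 20 glycolysis genes (left) and the 20 fibroblast and stromal markers (right) in each of the 8 arrays (x axes, group and replicate; blue marks arrays without co-culture or with the control hairpin, red the others). The glycolysis median of shRNA_control replicate 2, 10.8, was the highest of the 8 arrays.

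The other lists were not called by camera in this comparison. Small sets passed when adjusted over the list alone: the Notch regulator DTX1 rose (0.93) and NOTCH1 fell (-0.62) among 17 Notch targets (median -0.06, camera adjusted p = 0.642), and TRAF1 rose (1.19) and CCR7 fell among 19 NF-kB targets (median -0.07, adjusted p = 0.740). CD2 fell (-0.98) among 21 TCR complex genes (median 0.14, adjusted p = 0.189). EOMES (0.99) and GZMB (1.16) rose and TBX21 (-0.66) fell among 9 NK and cytotoxic markers (median 0.06, adjusted p = 0.642). TIMP1 (-0.93) fell among 20 fibroblast and stromal markers (median 0.01, adjusted p = 0.642). Of these, 0 passed over all genes by limma; the 5 lists, added up, held 9 higher and 6 lower at an unadjusted p under 0.05. The medians of the remaining lists were -0.09 for TCR-induced transcripts (adjusted p = 0.366), -0.02 for pro-apoptotic genes (0.969), -0.11 for anti-apoptotic genes (0.305), -0.03 for the cell cycle (0.256), 0.08 for MYC targets (0.642). They were 0.12 for T-cell leukemia transcription factors (0.461), 0.06 for the interferon response (0.642), 0.10 for p53 targets (0.642), -0.05 for cholesterol synthesis (0.642), -0.27 for the ER stress list (0.0757) and -0.05 for B-cell and myeloid markers (0.740). By limma 0 of their members passed over all genes or adjusted over the list alone, with 6 higher and 10 lower, added up, at an unadjusted p under 0.05. The ER stress list was called by camera in the fit of only the 2 groups (adjusted p = 0.0273), with no dim filter (0.00938), the mean of a gene's probe sets (0.0370) and array weights (0.0218). It was also called without either no_TCR_activation array (0.0464) and without shRNA_control replicate 1 (median -0.42, 5.99e-04), while without shRNA_control replicate 2 its median was 0.09 (0.945). With an estimated correlation it was not called in the full fit (adjusted p = 0.866) or without any array (0.743 without shRNA_control replicate 1). Other lists called with an array left out were MYC targets without shRNA_control replicate 1 (median 0.25, 0.00140), NK and cytotoxic markers without shRNA_control replicate 2 (0.0363), T-cell leukemia transcription factors without shRNA_TLX1 replicate 1 (0.0404), and the cell cycle (0.0216) and cholesterol synthesis (0.0214) without shRNA_TLX1 replicate 2. With an estimated correlation 0 lists were called without any single array in this comparison, with 0 at an unadjusted p under 0.05 and a lowest adjusted p of 0.542. The TCR complex list was called with the mean of a gene's probe sets (0.0379). Without shRNA_control replicate 2 the MYC list turned to -0.19 (adjusted p = 0.00601). With an estimated correlation camera called 0 lists in this comparison, with 0 at an unadjusted p under 0.05. The directional test of fry called 0, with 1 at an unadjusted p under 0.05, and its mixed test called 2.

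The third comparison asked whether TCR activation and TLX1 targeting changed the same genes. The metalloprotease gene ADAMTS17 was the 1 gene past the threshold in both, and it moved in opposite directions (-1.24 and 2.64). By limma 0 genes passed in both in the same direction, where independent lists give 0.0394, and 1 in opposite directions, where they give 0.0348. At an unadjusted p under 0.05 in both, 25 genes were higher in both (22.0 from independent lists), 46 lower in both (21.5), 35 higher with TCR activation and lower with the hairpin (24.9) and 40 the reverse (19.0), which makes 71 in the same and 75 in opposite directions. Both comparisons use the same spread for each gene, so genes of small spread pass in both whatever their direction. The counts from independent lists are therefore not the values without a shared change, and no test of the overlap is given. Across the 13102 genes the log2 changes of the 2 comparisons correlated at Pearson's r = 0.06 and Spearman's rho = 0.04, with a covariance of 0.00370.

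The 2 responses differed, by the test of the difference itself, for 50 genes: 30 with a more positive change under TCR activation and 20 with a more negative one, 5 of the 20 on chromosome Y, among 1145 at an unadjusted p under 0.05. The largest differences were those of RNASE2 (5.15, adjusted p = 1.53e-05), VAMP8 (3.74), PRTN3 (3.50), DEFA4 (3.29) and MGST1 (3.10). On the other side, with chromosome Y genes left out, stood ADAMTS17 (-3.88, limma adjusted p = 0.00133), CD55 (-2.50), ID2 (-2.31), ECRG4 (-2.18) and ADTRP (-2.15). The first 5 and ADAMTS17 passed whichever array was left out. The others lost their call under at least 5 of the 8 left-out arrays, with an adjusted p of up to 0.190 for CD55 and 0.205 for ADTRP without no_TCR_activation replicate 2, 0.275 for ID2 without TCR_activation replicate 2, and 0.145 for ECRG4 without TCR_activation replicate 1. Of the lists, cell cycle (0.22, camera adjusted p = 3.21e-04; adjusted p = 0.552 with an estimated correlation) and glycolysis (0.66, camera adjusted p = 1.79e-05; adjusted p = 0.659 with an estimated correlation) differed. The glycolysis difference was 0.13 (adjusted p = 0.0446; 0.848 with an estimated correlation) without shRNA_control replicate 2. Other lists differed under some settings at the preset correlation, while with an estimated correlation 0 of the 19 lists differed in the full fit. The ER stress list did with no dim filter (0.0251), the mean of a gene's probe sets (0.0320), array weights (0.0347), without no_TCR_activation replicate 2 (0.0132) and without shRNA_control replicate 1 (9.22e-04). The post-selection list did with the mean of probe sets (0.0291), array weights (0.0207), without no_TCR_activation replicate 2 (0.0321) and without shRNA_control replicate 2 (0.0446). Without the latter array, MYC targets (2.86e-05), NF-kB targets (0.00692) and TCR-induced transcripts (0.0265) differed too. TCR-induced transcripts also differed without no_TCR_activation replicate 1 (0.00119), NF-kB targets (0.0291) and TCR complex genes (0.0436) with the mean of probe sets, and MYC targets, interferon response and cholesterol synthesis without shRNA_TLX1 replicate 2 (0.0444 each). With an estimated correlation camera called 0 lists without any single array, with 0 at an unadjusted p under 0.05 and a lowest adjusted p of 0.535. The count was 14 without TCR_activation replicate 1, 17 without its replicate 2, 21 and 19 without no_TCR_activation replicates 1 and 2, 21 and 27 without shRNA_TLX1 replicates 1 and 2, and 908 and 132 without shRNA_control replicates 1 and 2.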

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

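The explanations weighed in this part, and the criteria for them, were chosen after the data had been seen. The fits without single arrays and the test of the stromal list were planned before. Probe sets that the platform annotation lists with several genes or with none lie outside the gene comparisons, and a signal in them was the reason for a closer look: of 6029 such probe sets past the dim filter, 15 passed the threshold with TCR activation (8 higher, 7 lower) and 2 with the TLX1 hairpin (2 higher), against 0 control probe sets in either.

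Granule genes were higher in the co-cultured arrays, and RNA of myeloid cells was weighed as a technical source. The upper quartile of the change of 23 general myeloid genes, dim genes included, was 0.398, below the bound of 1 set after the data had been seen. Some members were higher, such as S100A9 (4.13 and 5.36 without and with co-culture) and MNDA (3.47 and 4.79), and most read low throughout. The brightest members went both ways, with AIF1 at 11.04 and 11.43 and MPO at 8.69 and 7.97. Such RNA is therefore not excluded. A change within the leukemia cells and a difference between the cultures unrelated to the TCR remain open as well. Over all 22 granule genes with a probe set, dim genes included, the median change was 0.301 and the upper quartile 2.28, so the rise was confined to part of the list.

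Chromosome Y genes were lower in the co-cultured arrays, with 6 of 16 tested past the threshold at a median of -4.37, and a median of -0.03 for the same genes with the TLX1 hairpin. A share of cells of another type without a Y chromosome would have to be 95.2% for this fall. The lower quartile of the TCR complex list was -0.14, which counts against dilution by cells that lack T cell transcripts. It cannot decide on T-lineage cells without a Y chromosome. For a different subline under the 2 labels, 2 versions of the test were run: in the first, 5 of 12 genes above the array median fell past the threshold, which counts against it as worded. That gene set held genes near background, which had little room to fall, so the count cannot decide the question. The gene set and the bound were replaced after the result was seen. In the second version 6 of 6 genes were lower by at least 1 on the log2 scale, 5 of them past the threshold. Their changes ran from -2.57 to -5.33. Because the second version was shaped by the first result, and a subline would be confounded with group, a subline is left open. No biological explanation was tested.

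TCR-induced, NF-kB and Notch lists were lower in the arrays labelled TCR activation. Receptor engagement would raise the first 2, and the Notch ligand on the stroma could raise the Notch list. These calls hold at the preset correlation only: with an estimated correlation the camera adjusted p of each list was 0.394. The larger adjusted p of the TCR-induced and NF-kB lists was 0.0192 without no_TCR_activation replicate 2, but the TCR-induced median went from -0.25 to -0.12 and the NF-kB median from -0.22 to -0.18, so the part of that array is left open. The Notch list lost its call without it (0.0751) and without replicate 1 (0.0524), but its median of -0.10 was -0.13 and -0.14 there, so the lost calls are no sign that a single array set it, and the question is left open. Exchanged labels could be tested only through the stromal list, whose camera p of 0.988 comes from arrays that offset each other: its medians were 5.93 and 6.32 without co-culture and 6.55 and 5.98 with it. Over all probe sets, arrays of the same TCR group correlated at r = 0.997 to 0.998 and arrays of different TCR groups at 0.993 to 0.995. This argues against single arrays exchanged between the groups, as far as co-culture is what divides these arrays. Stromal RNA in an array labelled without co-culture, or labels exchanged for whole groups, is not excluded, and either would change what the TCR group means stand for.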

How the results depend on the processing

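With 2 arrays per group, the counts depended on how the spread was estimated, and the cause was not tested where none is given. Against 81, 12 and 50 genes for TCR activation, the TLX1 hairpin and the difference, a fit of only the 2 groups gave 866 and 0, array weights gave 1350 and 1 for the first 2, the stricter dim filter gave 36 for the first and 26 for the difference, and an adjusted p under 0.01 gave 40, 0 and 18. Genes changed the same way in both numbered 1 instead of 0 with no dim filter, with the mean of a gene's probe sets and with eBayes trend. For some genes all kept probe sets showed the same change. These included the 7 of MAP3K20 (-2.08) and the 2 of BNIP3 (-1.35) with TCR activation, and the 3 of MAP2K2 (1.25) with the TLX1 hairpin. The cause was not tested, and for such genes the alternatives by probe set are no separate check. With each array left out in turn, the counts ranged from 29 to 217, 0 to 1796 and 14 to 908, those changed the same way from 0 to 34, the correlation of the responses from -0.0392 to 0.0959 (r), and the TLX1 change from -0.73 to -0.34. The groups left with 1 array were assumed to vary like the others.

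The replicate block gave 73, 9 and 59 genes. It ended the calls of 9 of the 12 genes named for the TLX1 hairpin (all but ADAMTS17, ID2 and CCR9; adjusted p from 0.0625 to 0.0821), of 6 named for TCR activation (YOD1, ECRG4, BCL2L11, FOXO1, PFKM and ADAMTS17, the gene shared by both comparisons, at 0.0555) and of ECRG4 for the difference. It added those of HES1 for TCR activation (0.0289) and CCR7 for the TLX1 hairpin (0.0447). Replicate numbers did not show that arrays pair in the TCR experiment, where deviations of same-numbered arrays correlated at -0.14. In the hairpin experiment they correlated at 0.35. There the actin 3′ minus 5′ signal was 0.57 (control) and 0.66 (TLX1 hairpin) for replicate 1. It was 0.81 and 0.83 for replicate 2. Likewise, shRNA_control replicate 1 correlated more with shRNA_TLX1 replicate 1 (r = 0.994) than with shRNA_control replicate 2 (0.986). But shRNA_TLX1 replicate 2 correlated more with shRNA_TLX1 replicate 1 (0.993) than with shRNA_control replicate 2 (0.989). Pairing of the hairpin arrays is therefore left open. Crossing the numbers of the TCR experiment, chosen after seeing the data, gave 71 genes there and 59 for the difference.

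Of the lists, 2 reversed. Stromal markers changed by -0.10 without TCR_activation replicate 1 and by 0.21 without its replicate 2. MYC targets with the TLX1 hairpin changed by 0.25 without shRNA_control replicate 1 and by -0.19 without its replicate 2. The other list results kept their verdict in 1000 cases, lost the call in 23, gained it in 32 and moved in 64. The named genes kept their verdict in 3325 cases, lost the call in 258, gained it in 128 and moved in 15, with 0 reversed. A list or gene that was not called and stayed so counts as kept, and only a called one can lose its call. The kept counts therefore do not measure how stable the calls were. Signal near background limits what the dim genes can show.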

Other observations

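All 4 lists in this part were written after the data had been seen, and the genes named were chosen after their values were seen. Of 22 granulocyte granule genes with a probe set, 12 passed the dim filter. In the co-cultured arrays 8 of these rose, 0 fell and 4 did not pass the threshold. By sign, 9 of the 12 were higher and 3 lower. Over all 22 the median change was 0.301, with quartiles of 0.0166 and 2.28. Over the 12 it was 2.08, but genes such as RNASE2, PRTN3, MS4A3 and S100A8 passed the filter only through the co-cultured arrays, and the list was picked for its rise. For this reason no test is given for any of the 4 lists. With the TLX1 hairpin the median of the 12 was -0.10. Among single genes, the granulocyte progenitor gene MS4A3 rose by 2.64, the calcium-binding S100A8 by 2.49, the adhesion molecule CEACAM6 by 1.66 and the granule protease CTSG by 1.52. The first 3 read below the array median without co-culture on average, so the sizes of their rises are not exact. Other markers of the lineage differed. Without and with co-culture, MPO stood at 8.69 and 7.97, CAMP at 5.86 and 5.84, LCN2 at 5.59 and 5.72 and LTF at 4.67 and 4.54. In the same order, ELANE stood at 3.52 and 3.56, the myeloid factor SPI1 at 4.48 and 4.53, S100A9 at 4.13 and 5.36 and MNDA at 3.47 and 4.79. LYZ stood at 4.18 and 4.24 by its main probe set and at 3.25 and 4.49 by another, and CYBB, below the array median without co-culture, rose by 0.83 (adjusted p = 0.0284). The 9 tested general myeloid genes had a median of 0.12, with 1 past the threshold.

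Stress lists differed between single arrays. Heat shock genes changed by a median of -0.13 over 15 genes in the TCR comparison, with 1 fallen, by -0.02 without no_TCR_activation replicate 2 and by -0.29 without its replicate 1. Hypoxia genes changed by -0.30 over 20 genes with TCR activation and by -1.27 with the TLX1 hairpin, the latter being -0.25 without shRNA_control replicate 2 and -1.98 without its replicate 1.

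Stromal markers differed within the TCR groups. The list was 0.21 higher in no_TCR_activation replicate 2 than in replicate 1, and 0.28 higher in TCR_activation replicate 1 than in replicate 2, each a difference between 2 single arrays. Both lay at percentile 100 of 10000 random lists, but random lists ignore the correlation between genes and the order of the arrays was chosen after the values were seen, so this is not used as a test. The list medians of the 4 arrays of the TCR experiment were 5.93, 6.32, 6.55 and 5.98, against 5.22 to 5.37 in the hairpin arrays. The arrays were kept in the groups the labels give.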
